A study of Mus musculus with 8 samples.

How the data were processed

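Total RNA from sorted tumour-associated macrophages was measured on single-channel arrays with biotin end-labelling, per the labels' protocols, in 4 Cre- and 4 Cre+ samples taken 6 weeks after tumour implantation. The deposited table holds 1 value per probe set and array for 35556 probe sets, on a scale that the values themselves place as log2. The summarization and normalization the authors used for these deposited log2 values, and the base of the logarithm, are not given in the sources used here; base 2 was assumed, so fold changes rest on that. The array medians lie close together but the quartiles differ, so the deposited values do not share one distribution. The table holds no detection calls or background values, so the depth of a value cannot be given and only the number of arrays limits the precision as far as it is known.

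Probe sets were named through GEO's annotation of the platform: 21789 had 1 gene symbol, 1621 had several and 12146 had none. The gene IDs of 21698 probe sets matched the reference gene table of the mouse assembly GRCm38.p6, and none was renamed. That table served only for names and for which genes neighbour each other, and no positions are given because no build is named for the array values. Only probe sets with 1 symbol were named; for the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 19938 genes.

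The groups were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without trend and not robust, on the deposited values with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No filter was set on dim probe sets. Abca1, Abcg1, Lyz1 and Lyz2 were also compared by an exact two-sided permutation test over 70 splits, whose smallest p is 0.0286. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over 28 lists; lists with fewer than 5 measured genes were not tested. Of these lists 13 passed, 11 higher and 2 lower; with the correlation estimated from the data none passed, the smallest adjusted p was 0.0953, and 6 had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move one way on balance and does not compare them with other genes, passed 18.

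The gene lists, the rule for named genes, the tests above and all alternatives were fixed before the data were examined, except that the array spread as a covariate, and its permutation test between the groups, were added afterwards. The lists were LXR targets, SREBP2 targets, alternative activation, interferon gamma response, type I interferon response, inflammatory cytokines and NF-kB targets, MHC class II presentation, vascular, matrix and immunosuppressive factors, lipid-laden macrophage genes, fatty acid synthesis, lysosome, cell cycle, unfolded protein response, glycolysis and hypoxia, oxidative phosphorylation, immediate early and handling stress genes, and markers of 13 cell types, besides sex-linked genes as a check. Named were the targeted and lysozyme genes, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of smallest p in each list; predicted genes, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were left out of the largest changes.

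The alternatives were quantile normalization, median centring of each array, filters at the median (50th percentile) and 25th percentile of gene level, the mean or the most variable probe set of a gene, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array in turn, all probe sets, and camera with an estimated correlation or fry. The fits were tested on simulated data with each gene's own spread within groups, in which 200 of 19938 genes were changed for this comparison: 69% of 2-fold and 87% of 4-fold changes were recovered, with 5.45% false calls. The simulation drew genes independently and gave both groups the same spread. It therefore does not cover correlation between genes or a difference in spread between the arrays of the groups. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).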

Results

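The series profiled macrophages sorted from tumour-bearing mice whose Abca1 and Abcg1 genes carry loxP sites (fl/fl). The mice lacked or carried a Cre recombinase driven by the lysozyme M promoter, which is active in myeloid cells. ABCA1 and ABCG1 are membrane transporters that move cholesterol out of macrophages to apolipoprotein A-I and high-density lipoprotein. Cells were collected 6 weeks after tumour implantation. The sort kept macrophages bearing CD45.2, CD11b, CD64 and Tim4, a phosphatidylserine receptor of long-lived tissue-resident macrophages. Cells bearing NK1.1, Ly6G, CD5 or CD19 were removed. RNA from 4 Cre- and 4 Cre+ samples was hybridised to one single-channel array each, which gave 35556 probe sets and 19938 named genes per array. The array medians lay between 3.21 and 3.49 on the deposited log2 scale, and the precision of each comparison is limited by the number of arrays. Correlations between arrays over all probe sets ran from 0.903 to 0.987, and the first principal component over genes, with 47.9% of the variance, separated the groups. Values were spread more widely on the Cre+ arrays, with a standard deviation over probe sets of 2.09 ± 0.031 (SD, n = 4) against 1.95 ± 0.065 (SD, n = 4) on the Cre- arrays (exact permutation test, two-sided, p = 0.0286, the smallest this design allows). Cre- replicate 1 stood apart from the rest of its group, with a mean correlation of 0.921 to the other Cre- arrays. The other Cre- arrays had 0.935 to 0.942 with their own group, and the Cre+ arrays 0.970 to 0.978 with theirs. Cre- replicates 2 and 4 correlated slightly more with the Cre+ arrays (0.946 each) than with their own group (0.940 and 0.942). Cre- replicates 1 and 3 correlated less with the Cre+ arrays (0.906 and 0.934). The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

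**Figure D1:**
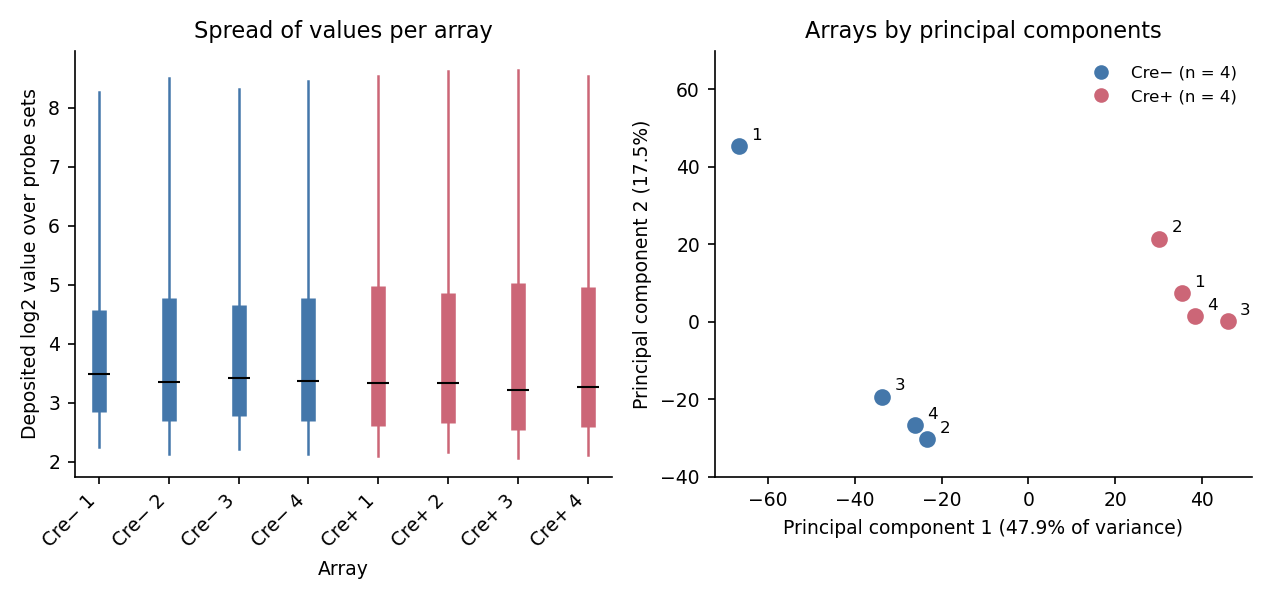
Left, deposited log2 values over all probe sets of each array (line from the 5th to the 95th percentile, box from the lower to the upper quartile, bar at the median). Right, the 8 arrays on the first 2 principal components over genes, numbered by replicate; the Cre- and Cre+ arrays lie apart on component 1, which holds 47.9% of the variance, and Cre- replicate 1 lies away from the other Cre- arrays.

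The targeted genes were examined first. Abcg1 measured 5.46, 6.02, 4.99 and 5.79 on Cre- replicates 1 to 4 and 4.77, 4.66, 4.97 and 4.80 on Cre+ replicates 1 to 4, so that every Cre+ value lay below every Cre- value. The mean log2 difference of Abcg1, Cre+ minus Cre-, was -0.76 (SE 0.21, limma adjusted p = 0.0619), which did not pass the threshold of 0.05 over all genes. The exact two-sided permutation test gave p = 0.0286, the smallest value the 70 splits allow. Abcg1 passed after quantile normalization (difference -1.11, adjusted p = 0.0131), with array weights (-0.81, 0.0337) and without Cre- replicate 3 (-0.95, 0.0186). These were 3 of 16 alternative fits, which leave out the replicate block and the array spread. Abcg1 did not pass after median centring (-0.64, adjusted p = 0.125) or with the array spread as a covariate (-1.40, 0.126). Abca1 measured 6.45, 5.79, 6.15 and 6.46 on the Cre- arrays and 6.94, 6.15, 6.82 and 6.39 on the Cre+ arrays, a difference of 0.36 (SE 0.22, limma adjusted p = 0.259; exact permutation p = 0.257). It was -0.035 after quantile normalization. The labels do not state which exons are floxed, and each probe set summarises a whole transcript, so probes outside the deleted parts tell nothing about the deletion. Lyz2, the lysozyme gene whose locus carries the Cre transgene, had a mean of 12.10 ± 0.059 (SD, n = 4) in Cre- and 11.93 ± 0.077 (SD, n = 4) in Cre+, and the difference of -0.17 did not pass (adjusted p = 0.190). For its neighbour Lyz1 the difference was -0.53 (adjusted p = 0.137).

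**Figure D2:**
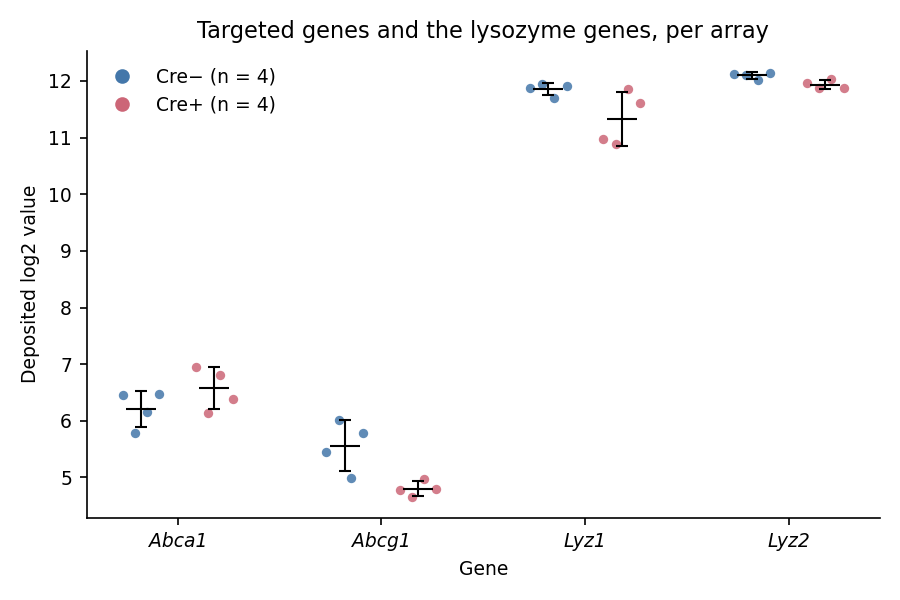
Deposited log2 values of Abca1, Abcg1, Lyz1 and Lyz2 on each of the 4 Cre- and 4 Cre+ arrays (points), with the mean and SD of each group (bars). The Abcg1 values of the Cre+ arrays, 4.66 to 4.97, lie below those of the Cre- arrays, and the Abca1 values of the groups overlap.

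The main comparison asked how gene expression in tumour-associated macrophages differs between mice with and without the Cre that targets Abca1 and Abcg1. Of 15 resident macrophage genes 12 were higher in Cre+ macrophages, as were 16 of 30 cell cycle genes, and none of either list was lower. The monocyte chemokine receptor gene Ccr2, the folate receptor gene Folr2 and 5 of 9 MHC class II genes were lower. As lists, these 3 passed camera, but none did with an estimated correlation (adjusted p = 0.0953 for the resident list and 0.185 for the others). The largest rise was that of Lbp, which encodes the lipopolysaccharide-binding protein, from 4.09 ± 0.96 to 9.72 ± 0.21 (SD, n = 4 each), a log2 difference of 5.63 (SE 0.42, adjusted p = 4.1e-04). It was followed by Vsig4, a complement receptor of tissue macrophages (5.59, SE 0.90), Itga6, which encodes integrin alpha 6 (5.44, SE 0.38), Aspa, which encodes aspartoacylase (3.34 ± 0.44 to 8.34 ± 0.33; SD, n = 4 each), and the surface receptor gene Cd93 (4.99, SE 0.36). Vsig4 varied widely within Cre- (7.47, 3.51, 6.08 and 3.04 on replicates 1 to 4), against 10.32 to 10.86 in Cre+, so its mean rise describes single Cre- arrays poorly. The other 7 of the 12 largest rises ran from 4.79 down to 4.21. They were those of Cd5l, a secreted macrophage protein gene, Cd9, a tetraspanin gene, Egln3, a prolyl hydroxylase gene of the hypoxia response, and Stfa3. Arg1, the arginase gene, Gpnmb, a glycoprotein gene of lipid-laden macrophages, and Tlr13, a receptor gene for bacterial ribosomal RNA, completed them. Stfa3 is one of several closely similar stefin A genes, and cross-hybridization among them was not checked. Ccr2 fell from 9.25 ± 0.34 to 3.62 ± 0.30 (SD, n = 4 each), a difference of -5.63 (SE 0.21, adjusted p = 3.1e-05). Falls of similar size were measured for Fcrls, an Fc receptor-like gene (-5.30, SE 0.41), Cd226, an adhesion receptor gene (-5.06, SE 0.26), F13a1, which encodes the A chain of coagulation factor XIII (-4.69, SE 0.42), and Emb, which encodes embigin (-4.64, SE 0.43). The other 7 of the 12 largest falls, from -4.27 to -3.13, were those of Plbd1, Gfra2, Folr2, Socs6, Clec4b1, Cd2 and Plxnd1. Several of these genes lay near or below the array medians (3.21 to 3.49) in the group with the lower value. Examples are Ccr2 (3.62), Gfra2 (3.61) and Clec4b1 (2.61) in Cre+ and Gpnmb (3.24) in Cre-. Background values are not given, so the size and rank of such differences are uncertain.

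In all, 1526 of 19938 genes (7.65%) passed limma's adjusted p of 0.05, 956 of them higher and 570 lower in Cre+, and 6653 genes had an unadjusted p under 0.05. Among the calls, 611 genes rose and 77 fell by more than 2-fold, and 153 rose and 28 fell by more than 4-fold. The groups did not overlap for 4783 genes (24.0%), where chance gives 2.86% if all arrays are interchangeable. Array spread also differed between the groups, so the excess cannot be read as a count of changed genes. Predicted genes, small RNAs, olfactory receptors and antigen receptor segments, which are not named here, made up 28 of the higher and 73 of the lower calls. Of the 91 called genes with several probe sets, 80 had differences of the same sign in all of them, past the threshold or not. None had another probe set past the threshold the other way. The median log2 difference over all genes was -0.12, and centring each array on its median moved it to -0.0091. The calls were then 1212 higher and 224 lower, or 84.4% higher against 62.6%. In the main fit the shift depended on gene level. Of 10 classes of genes ordered by mean level, the 5th had a median difference of -0.22, with 32 calls higher and 108 lower. The 9th had 0.41, with 233 higher and 38 lower. After quantile normalization these medians were -0.089 and 0.0087. How many calls follow this shift was not tested. The number of calls was 583 without Cre+ replicate 1, 515 without Cre+ replicate 3 and 537 without Cre+ replicate 4, and it was 996 after quantile normalization and 143 with the spread of each array as a covariate. Of the 24 genes named above, 23 passed in each of 16 alternative fits, which leave out the replicate block and the array spread. With the array spread as a covariate 17 of the 24 passed, and Cd9, Stfa3, Arg1, Tlr13, Folr2, Cd2 and Socs6 did not (adjusted p 0.0578 to 0.155). Of all 76 genes named by rule that passed, 30 did so with that covariate. The call of Socs6, the exception in the 16 fits, ended without any one array other than Cre- replicate 3 (adjusted p 0.0592 to 0.0918).

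**Figure D3:**
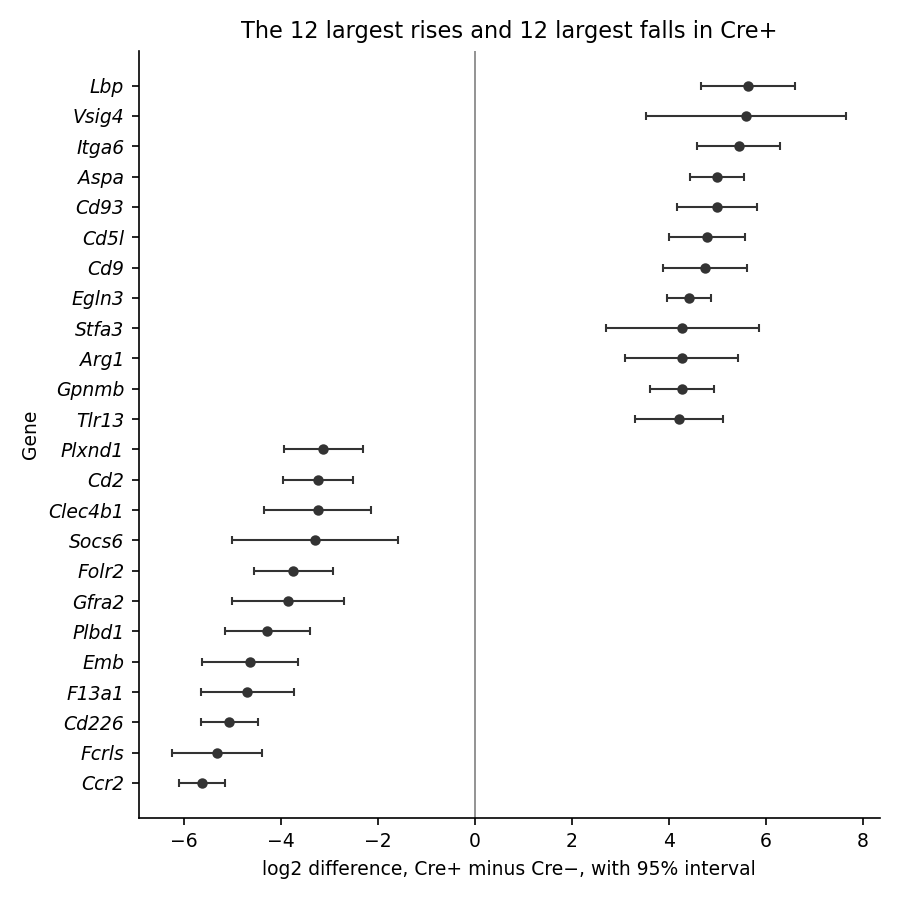
log2 difference, Cre+ minus Cre-, with its 95% interval from limma, for the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap (4 arrays per group). Lbp at 5.63 and Ccr2 at -5.63 lie at the ends.

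Gene lists for pathways and cell types were compared next, and 13 of 28 passed camera, 11 higher and 2 lower in Cre+. None passed with an estimated correlation (smallest adjusted p = 0.0953; 6 lists at unadjusted p under 0.05), and fry passed 18. The resident macrophage, cell cycle and MHC class II lists passed in all 18 alternative fits, and these 3, the LXR targets and the lipid-laden macrophage genes also passed after quantile normalization. Efflux through ABCA1 and ABCG1 lowers cell cholesterol. Cholesterol derivatives activate the liver X receptors (LXR), and cholesterol holds back SREBP2, the activator of cholesterol synthesis genes. Among 14 measured LXR targets other than Abca1 and Abcg1, 4 rose, none fell and 10 did not pass. Mylip, whose product directs degradation of the LDL receptor, rose from 4.31 ± 0.51 to 6.49 ± 0.22 (SD, n = 4 each; difference 2.18, SE 0.25, limma adjusted p = 0.00252). The stearoyl-CoA desaturase genes Scd2 and Scd1 rose by 2.78 (SE 0.40, adjusted p = 0.00689) and 2.44 (SE 0.48, adjusted p = 0.0247). Lpcat3, which encodes a phospholipid acyltransferase, rose by 0.96 (SE 0.19, adjusted p = 0.0241). Adjusted over the list alone, 7 were higher and 1 lower. The list as a whole was higher by a mean of 0.79 (camera adjusted p = 2.7e-04; adjusted p = 0.185 with an estimated correlation). Its call ended when only genes at or above the median level were tested (adjusted p = 0.0684) and with the array spread as a covariate (adjusted p = 0.191). Of 20 measured cholesterol synthesis and uptake genes under SREBP2, none rose, 2 fell and 18 did not pass, with the same count adjusted over the list alone. Sqle, which encodes squalene epoxidase, fell from 4.68 ± 0.11 to 3.69 ± 0.16 (SD, n = 4 each; difference -0.98, SE 0.11, limma adjusted p = 0.00249). Srebf2, the gene of SREBP2, had a difference of -0.70 (SE 0.14, adjusted p = 0.0284). For Hmgcs1 and Pmvk, enzymes of the mevalonate pathway, the differences were -0.30 (SE 0.14, adjusted p = 0.163) and -0.24 (SE 0.13, adjusted p = 0.231). The list's mean difference of -0.14 did not pass (camera adjusted p = 0.514), except with the array spread as a covariate (adjusted p = 0.00352). For 3 of the genes named here the call ended without single arrays, while the difference stayed within 0.81 to 1.10 for Lpcat3, 2.19 to 2.93 for Scd1 and -0.82 to -0.63 for Srebf2. The call of Lpcat3 ended without Cre+ replicate 1, 3 or 4 (adjusted p 0.0691 to 0.0772) and after quantile normalization (0.0566). That of Scd1 ended without Cre- replicate 1 or 3 or Cre+ replicate 1, 3 or 4 (0.0522 to 0.0775). That of Srebf2 ended without any one array other than Cre- replicate 3 (0.0523 to 0.0778) and after median centring (0.0621). Srebf2 passed in 7 of 16 alternative fits, the replicate block and the array spread left out.

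Macrophage activation genes moved in opposite directions within single lists. Of 25 measured genes of alternative activation by interleukin 4, 4 rose, 5 fell and 16 did not pass; adjusted over the list alone, 4 were higher and 7 lower. Arg1, which encodes the arginine-degrading enzyme arginase, rose from 5.03 ± 0.60 to 9.30 ± 1.02 (SD, n = 4 each; difference 4.27, SE 0.51, limma adjusted p = 0.00308). Alox15, the gene of a lipoxygenase, rose by 3.26 (SE 0.29, adjusted p = 8.5e-04), and Tgm2, the gene of a transglutaminase, by 1.71 (SE 0.17, adjusted p = 0.00146). Alox15 is also counted in the resident macrophage list. Retnla, which encodes a secreted resistin-like protein, fell from 12.30 ± 0.13 to 9.86 ± 0.84 (SD, n = 4 each; difference -2.44, SE 0.37, limma adjusted p = 0.00875). The other 5 members past the threshold were chosen after their values were seen. They were the arginine transporter gene Slc7a2, which was higher (1.34, SE 0.32), and the lectin genes Mrc1 (-2.98, SE 0.61) and Mgl2 (-2.62, SE 0.46), the receptor gene Il4ra (-0.72, SE 0.15) and Cdh1 (-0.49, SE 0.11). The calls of Slc7a2 and Cdh1 ended without Cre- replicate 3 or any one Cre+ array (adjusted p up to 0.114 and 0.102) and after quantile normalization (0.173 and 0.0899). That of Mgl2 ended without Cre+ replicate 3 or 4 (up to 0.0528), and that of Mrc1 without Cre- replicate 2, 3 or 4 or Cre+ replicate 1 or 4 (up to 0.0745). That of Il4ra ended without Cre- replicate 1 or 3 or Cre+ replicate 1, 3 or 4 (up to 0.0877). The list as a whole did not pass (mean difference -0.19, camera adjusted p = 0.433).

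Of 28 measured genes of the interferon gamma response, 1 rose, 5 fell and 22 did not pass; adjusted over the list alone, 3 were higher and 8 lower. The falls were led by MHC class II genes, which serve antigen presentation to CD4 T cells. H2-Eb1 fell from 9.97 ± 0.30 to 7.03 ± 0.49 (difference -2.94, SE 0.25, limma adjusted p = 6.8e-04; SD, n = 4 each). The differences were -2.06 (SE 0.27) for H2-Aa, -1.96 (SE 0.20) for Cd74, the invariant chain gene, and -1.67 (SE 0.24) for H2-Ab1. Cd274, which encodes the checkpoint ligand PD-L1, was higher (4.48 ± 0.34 to 5.68 ± 0.48; SD, n = 4 each) and the chemokine gene Cxcl9 lower (-2.83, SE 0.71); both were chosen after their values were seen. The call of Cd274 ended without Cre- replicate 1, 3 or 4 or Cre+ replicate 2, 3 or 4 (adjusted p up to 0.0697) and after quantile normalization (0.0981). That of Cxcl9 ended without any one array other than Cre+ replicate 4 (up to 0.127) and after median centring (0.0627). The interferon gamma list as a whole did not pass (mean difference -0.45, camera adjusted p = 0.136), but it did after quantile normalization (adjusted p = 5.0e-04), after median centring (0.0379), with filters at the median (0.00171) and 25th percentile of level (0.0385), without Cre+ replicate 4 (0.00577) and by fry (0.0310). The 9 measured genes of MHC class II presentation, which share H2-Eb1, Cd74, H2-Aa and H2-Ab1 with that list, included 5 that fell, H2-DMa among them (-1.81, SE 0.17), none that rose and 4 that did not pass. Adjusted over the list alone, 6 were lower. The list mean was 7.58 ± 0.13 in Cre- and 6.33 ± 0.29 in Cre+ (SD, n = 4 each), a difference of -1.25 that passed (camera adjusted p = 2.5e-04; adjusted p = 0.185 with an estimated correlation).

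**Figure D4:**
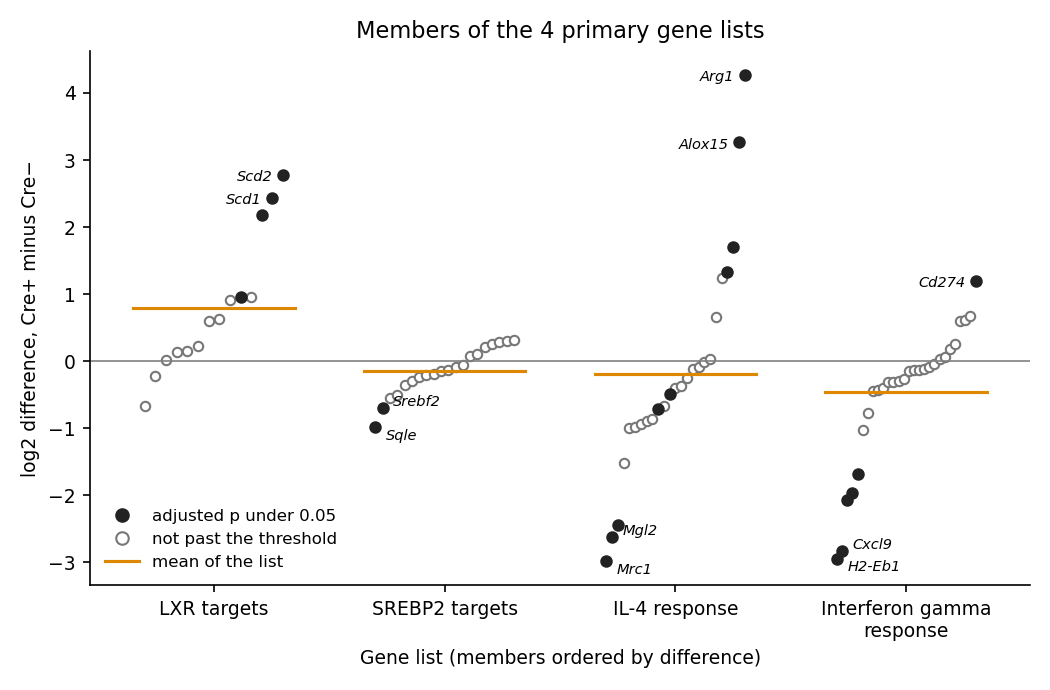
log2 difference, Cre+ minus Cre-, of each measured member of the 4 primary gene lists (points, ordered by difference within a list; filled where the gene passed an adjusted p of 0.05), with the mean of each list (line). The list means are 0.79 for LXR targets, -0.14 for SREBP2 targets, -0.19 for the interleukin 4 response and -0.45 for the interferon gamma response, and the last 2 lists hold members that changed in both directions.

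Genes of Tim4+ resident macrophages, as found in the peritoneal cavity, were mostly higher in Cre+. Of 15 measured members, 12 rose, none fell and 3, Rarb, Cxcl13 and Timd4, did not pass, and adjusted over the list alone 14 were higher. Tgfb2, a transforming growth factor gene, rose by 3.76 on the log2 scale (SE 0.22), Cd5l by 4.79 (SE 0.34), Cd93 by 4.99 (SE 0.36) and Ltbp1, the gene of a TGF-beta binding protein, by 3.36 (SE 0.25). Gata6, the transcription factor gene that defines large peritoneal macrophages, rose from 4.80 ± 0.79 to 7.35 ± 0.37 (SD, n = 4 each). It was chosen after its values were seen. Timd4, the gene of the Tim4 protein on which the cells were sorted, measured 9.74 ± 0.72 in Cre- and 9.86 ± 0.27 in Cre+ (SD, n = 4 each), a difference of 0.12 (SE 0.33, adjusted p = 0.791). The list mean was 6.46 ± 0.42 in Cre- and 9.36 ± 0.14 in Cre+ (SD, n = 4 each; camera adjusted p = 3.9e-17; adjusted p = 0.0953 with an estimated correlation). Monocyte genes split: of 9 measured, 3 rose, 2 fell and 4 did not pass, and the list did not pass camera (mean difference -0.32, adjusted p = 0.777), though fry, which does not compare it with other genes, placed it lower (adjusted p = 8.2e-05). Adjusted over the list alone, 3 were higher and 4 lower. Ccr2 and F13a1 fell, as above, while Mgst1, a glutathione transferase gene, and Plac8 rose by 3.10 (SE 0.42) and 4.06 (SE 0.69). The third rise was that of Treml4 (2.02, SE 0.47), chosen after its values were seen; its call ended without Cre- replicate 1, 3 or 4 or Cre+ replicate 1, 3 or 4 (adjusted p up to 0.0975) and after quantile normalization (0.0685). Of 9 general macrophage genes, 3 rose and 6 did not pass (4 higher and 3 lower adjusted over the list alone), and the list as a whole did not pass (mean difference 0.48, camera adjusted p = 0.181). Adgre1, the gene of F4/80, rose by 3.25 (SE 0.37), Itgam, the gene of CD11b, by 0.89 (SE 0.16) and Fcgr1, the gene of CD64, by 1.43 (SE 0.34), while the complement gene C1qb had a difference of -0.52 (adjusted p = 0.0558). After quantile normalization C1qb passed (-0.69, adjusted p = 0.0211), and the list then held 2 genes higher and 2 lower. The call of Itgam ended without Cre+ replicate 1 or 3 (adjusted p 0.0515 to 0.0585), and that of Fcgr1 after quantile normalization (adjusted p = 0.129) and without Cre- replicate 1, 2 or 4 or Cre+ replicate 2, 3 or 4 (0.0671 to 0.120).

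**Figure D5:**
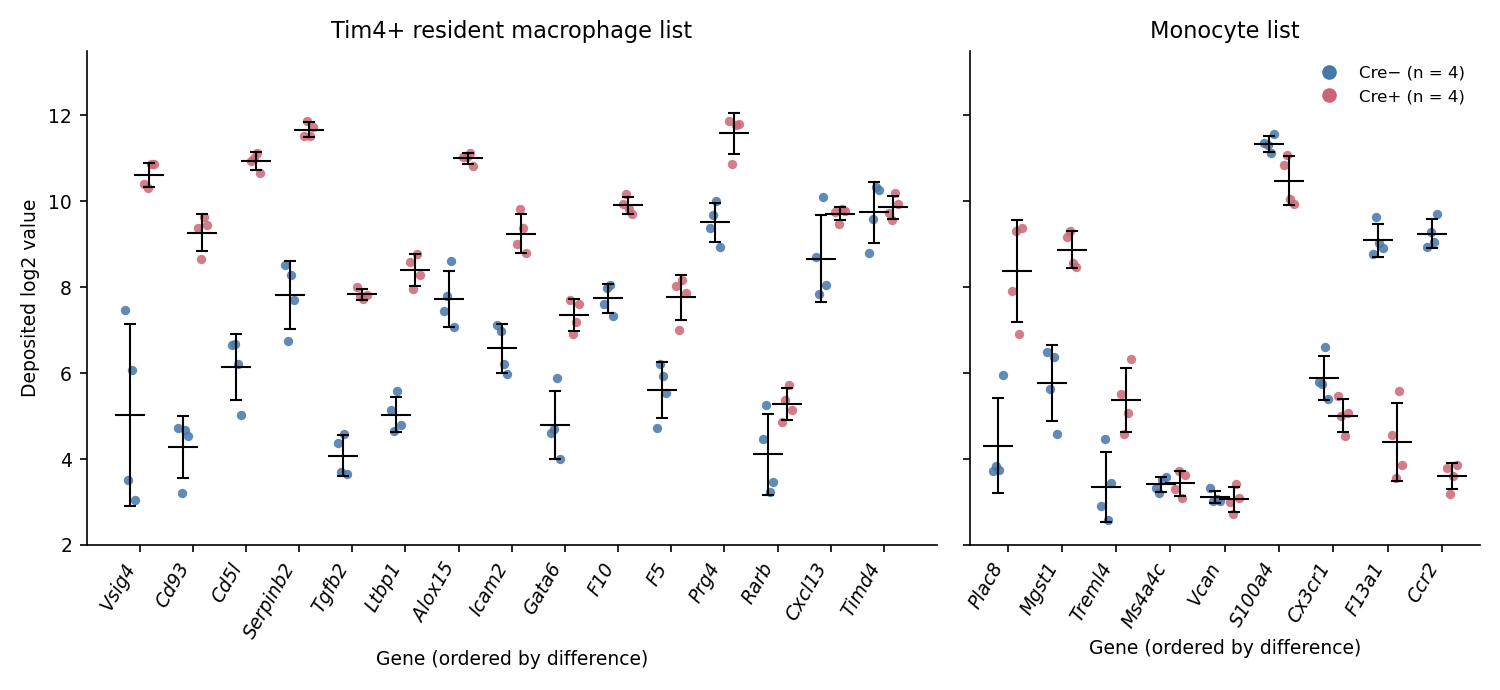
Deposited log2 values of the measured genes of the Tim4+ resident macrophage list (left) and the monocyte list (right) on each array (points), with the mean and SD of the 4 arrays of each group (bars), ordered by difference. All of the resident genes but Rarb, Cxcl13 and Timd4 passed the threshold and were higher in Cre+, while of the monocyte genes Ccr2 and F13a1 were lower and Mgst1, Plac8 and Treml4 higher.

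Cell division genes were higher in Cre+: of 30 measured cell cycle genes, 16 rose, none fell and 14 did not pass, and adjusted over the list alone 23 were higher. After quantile normalization 9 passed the threshold over all genes, all of them higher. Bub1, a spindle checkpoint kinase gene, rose by 2.63 (SE 0.27), Birc5, the gene of survivin, by 2.02 (SE 0.27), Rrm2, a ribonucleotide reductase gene, by 1.80 (SE 0.20) and Ccne2, a cyclin gene, by 1.48 (SE 0.21). The list mean was higher by 1.18 (camera adjusted p = 9.9e-17; adjusted p = 0.185 with an estimated correlation). Among 16 measured genes of lipid-laden macrophages, 4 rose, none fell and 12 did not pass (4 higher and 1 lower adjusted over the list alone): Cd9 (4.75, SE 0.38), Gpnmb (4.27, SE 0.29), and the fatty acid-binding protein genes Fabp5 (4.05, SE 0.47) and Fabp4 (3.46, SE 0.59). This list passed (mean difference 1.19, median 0.31, camera adjusted p = 2.6e-04; adjusted p = 0.185 with an estimated correlation), though not among genes at or above the median level (adjusted p = 0.0684). As listed, it shares Cd63, Lipa, Ctsb, Ctsd and Ctsl with the lysosome list and Apoe, Lpl and Plin2 with the LXR targets. Of 14 genes of fatty acid synthesis, 4 rose and 10 did not pass (5 higher and 1 lower adjusted over the list alone), with Acaca, the gene of acetyl-CoA carboxylase, higher by 2.53 (SE 0.28), the elongase gene Elovl5 by 1.24 (SE 0.19), and Scd1 and Scd2 as above. The mean of that list was 0.65 and its median -0.0048 (camera adjusted p = 0.0262; adjusted p = 0.222 with an estimated correlation), and it passed in 11 of 18 alternative fits. The call ended without Cre- replicate 1 (adjusted p = 0.117), after quantile normalization (mean 0.52, 0.202) and after median centring (0.0555). It also ended with filters at the median (0.0687) and 25th percentile of level (0.0939) and with the array spread as a covariate (mean 0.19, 0.787).

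The inflammatory, type I interferon, glycolysis and lysosome lists were higher by smaller amounts, and their calls ended when the arrays were given one distribution of values. After quantile normalization the mean difference was 0.38 for the inflammatory list, 0.32 for glycolysis and hypoxia, 0.25 for the lysosome and 0.099 for type I interferon. These 4 calls also ended among genes at or above the median level (adjusted p = 0.0952, 0.192, 0.0687 and 0.466 in that order) and with the array spread as a covariate (0.309, 0.143, 0.196 and 0.722). Of 30 inflammatory cytokine and NF-kB target genes, 5 rose, 1 fell and 24 did not pass (7 higher and 4 lower adjusted over the list alone), and the list mean was higher by 0.56 (camera adjusted p = 0.00273; adjusted p = 0.185 with an estimated correlation; 0.190 after quantile normalization). Il1a, the gene of interleukin 1 alpha, rose by 4.17 (SE 0.30), the chemokine gene Ccl3 by 3.53 (SE 0.49), the receptor gene Ccrl2 by 1.78 (SE 0.23) and Saa3, a serum amyloid gene, by 1.43 (SE 0.26), the last with its call lost without Cre+ replicate 1 or 4 (adjusted p 0.0528 to 0.0549). The fifth rise, of the chemokine gene Cxcl2 (2.60, SE 0.54), and the fall, of the cyclooxygenase 2 gene Ptgs2 (-0.74, SE 0.18), were chosen after their values were seen. The call of Cxcl2 ended without Cre- replicate 4 or Cre+ replicate 1, 3 or 4 (adjusted p up to 0.0885) and after quantile normalization (0.0609). That of Ptgs2 ended without any one array other than Cre- replicate 4 (up to 0.128), after quantile normalization (0.0617) and after median centring (0.0714). Of 16 glycolysis and hypoxia genes, 3 rose, 1 fell and 12 did not pass (4 higher and 1 lower adjusted over the list alone; mean 0.57, camera adjusted p = 0.00197; adjusted p = 0.185 with an estimated correlation; 0.209 after quantile normalization). Egln3 rose by 4.42 (SE 0.20), and the glycolytic enzyme genes Pfkl and Aldoa rose by 1.33 (SE 0.20) and 1.23 (SE 0.24), whereas Pkm, the pyruvate kinase gene, fell by 0.49 (SE 0.11). The call of Aldoa ended without Cre+ replicate 3 (adjusted p = 0.0724) and that of Pkm without any one array other than Cre- replicate 4 (0.0607 to 0.107) and after median centring (0.0643). Pkm passed in 4 of 16 alternative fits, the replicate block and the array spread left out. Of 24 lysosomal genes, 3 rose and 21 did not pass, with the same count adjusted over the list alone (mean 0.45, camera adjusted p = 1.3e-04; adjusted p = 0.185 with an estimated correlation; 0.070 after quantile normalization). The hydrolase genes Gaa and Gla rose by 1.99 (SE 0.24) and 1.83 (SE 0.36), and the call of Gla ended without any one Cre+ array (adjusted p 0.0504 to 0.0768). Ctsa, the cathepsin A gene, rose by 0.73 (SE 0.16), and its call ended after quantile normalization (0.0761) and without Cre- replicate 1, 3 or 4 or Cre+ replicate 1, 3 or 4 (0.059 to 0.0934). Of 27 type I interferon response genes, 2 rose and 25 did not pass (3 higher adjusted over the list alone; mean 0.34, camera adjusted p = 0.00248; adjusted p = 0.334 with an estimated correlation; 0.202 after quantile normalization; 0.144 by fry). Usp18 and Herc6, which encode a deconjugase and a ligase of ISG15-type modification, rose by 1.02 (SE 0.20) and 0.79 (SE 0.20). Neither passed after quantile normalization (adjusted p = 0.0694 and 0.149). The call of Usp18 ended without Cre- replicate 3 or Cre+ replicate 3 or 4 (0.054 to 0.077), and that of Herc6 without any single array (0.0535 to 0.128).

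Of 15 genes of the unfolded protein response, 1 rose, Herpud1 (1.32, SE 0.19, adjusted p = 0.0982 after quantile normalization), and 14 did not pass; 2 were higher adjusted over the list alone, and the list mean of 0.34 passed (camera adjusted p = 0.0055; adjusted p = 0.222 with an estimated correlation; mean 0.10 and adjusted p = 0.510 after quantile normalization). None of 27 genes of oxidative phosphorylation passed limma's threshold, over all genes or adjusted over the list alone, and the list mean was higher by 0.27 (camera adjusted p = 3.6e-04; adjusted p = 0.222 with an estimated correlation; mean 0.027 and adjusted p = 0.589 after quantile normalization; 0.0710 by fry); Ndufa4 had the smallest p of its members (difference 0.65, SE 0.19, adjusted p = 0.071). Both lists' calls also ended among genes at or above the median level (0.210 and 0.224) and with the array spread as a covariate (0.908 and 0.407). Of 18 genes of vascular, matrix and immunosuppressive factors, 4 rose, 1 fell and 13 did not pass (5 higher and 2 lower adjusted over the list alone), and the list did not pass (mean 0.41, camera adjusted p = 0.114) except without Cre+ replicate 2 (0.0421) and by fry (0.0380). Arg1 and Cd274 rose as above, the thrombospondin gene Thbs1 by 3.31 (SE 0.57) and the elastase gene Mmp12 by 1.37 (SE 0.26), while Mmp9, the gene of gelatinase B, fell by 2.61 (SE 0.53). The call of Thbs1 ended without Cre+ replicate 3 (adjusted p = 0.0533), that of Mmp12 without Cre+ replicate 1, 3 or 4 (0.0537 to 0.0664), and that of Mmp9 without Cre- replicate 4 or any one Cre+ array (0.0537 to 0.0786). Of 15 immediate early and handling stress genes, none passed over all genes, 1 was higher and 2 lower adjusted over the list alone, and the list did not pass (mean -0.017, median 0.13, camera adjusted p = 0.600). After quantile normalization its mean was -0.32 and its median -0.30, and with the array spread as a covariate its mean was -0.26, without passing (adjusted p = 0.159 and 0.280). Fos differed by -0.56 (SE 0.15, adjusted p = 0.0554) and Ier3 by 0.92 (SE 0.26, adjusted p = 0.0677).

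Markers of other cell types were mostly at low values and slightly lower in Cre+, including those of cells that the sort removed. Among the T cell genes, Cd2 fell from 7.71 ± 0.58 to 4.48 ± 0.45 (SD, n = 4 each), whereas Cd3e measured 4.48 ± 0.32 and 4.06 ± 0.20 (SD, n = 4 each). Cd4, the second of the 2 T cell genes that fell among 8 measured (3 lower adjusted over the list alone), had a difference of -0.48 (SE 0.11), and its call ended after quantile normalization (adjusted p = 0.0778), after median centring (0.064) and without any one array other than Cre- replicate 2 (0.0594 to 0.101). The T cell list did not pass camera (mean -0.57, adjusted p = 0.181) except with a filter at the 25th percentile of level (0.0120), but it passed fry (0.00150). Of 7 NK cell genes, none passed limma's threshold over all genes and 4 were lower adjusted over the list alone; the list mean of -0.29 passed (camera adjusted p = 0.0319; adjusted p = 0.185 with an estimated correlation), though not after quantile normalization (0.202), with the array spread as a covariate (0.408) or without Cre- replicate 1 (0.0516). In the neutrophil list, S100a8, a calgranulin gene, rose by 3.78 (SE 0.34) and Retnlg and Camp fell, among 9 measured, 6 of which did not pass (the same adjusted over the list alone; list mean 0.18, median -0.23, camera adjusted p = 0.271). The call of Retnlg (-0.58) ended without Cre+ replicate 4 (adjusted p = 0.0575), and that of Camp (-0.37) after quantile normalization (0.222), after median centring (0.0953) and without any one array other than Cre- replicate 4 (0.0683 to 0.129). In the mesothelial and fibroblast list Msln fell and the other 9 genes did not pass, with the same count adjusted over the list alone (mean -0.23, camera adjusted p = 0.204), and the Msln call (-0.40) ended after quantile normalization (0.183), after median centring (0.152) and without any single array (0.0544 to 0.118). None of 7 B cell, 8 dendritic cell, 9 eosinophil and mast cell, 5 epithelial or tumour cell and 5 endothelial genes passed limma's threshold, with 1 B cell and 1 endothelial gene lower adjusted over the list alone; their mean differences were -0.29, -0.28, -0.15, 0.078 (median -0.031) and -0.27, and none of these lists passed camera (adjusted p = 0.158, 0.158, 0.211, 0.527 and 0.158). By fry the B cell, dendritic cell and endothelial lists were lower (adjusted p = 0.0102, 0.0427 and 0.0305). Alas2, the only erythroid gene measured, had a difference of -0.46 (SE 0.10, adjusted p = 0.0376), which did not pass after quantile normalization (0.108), after median centring (0.0763) or without any single array (0.0528 to 0.112). The Y-linked genes Uty, Eif2s3y and Kdm5d lay between 2.16 and 2.77 in both group means, and Xist, the X inactivation transcript, was present in Cre- (6.11 ± 0.78) and higher in Cre+ (8.27 ± 0.81; SD, n = 4 each; difference 2.16, SE 0.48, adjusted p = 0.0353), a call that ended after quantile normalization (adjusted p = 0.0646) and without any one array other than Cre- replicate 2 (0.0537 to 0.0816).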

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

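The tests of array spread and of Tim4 on the resident genes, and that of array spread on the cell cycle genes, were chosen only after the result was seen. The count of 1526 genes past the threshold was reached by 1 of the 35 distinct splits of the 8 arrays into groups of 4, the real one, and the highest count of any other split was 1. The real split would rank first by chance in 1 of 35 cases, the least this design allows, so the test cannot exclude chance. Mixed splits also hold the group difference within their groups, which lowers their counts. The labels name no processing batch, so none was tested.

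Resident macrophage genes other than Timd4 were higher in Cre+ by a mean of 3.10 over 14 genes. Of 9 monocyte genes, Ccr2 and F13a1 were lower and Mgst1, Plac8 and Treml4 higher, and that list did not pass camera (adjusted p = 0.777). A wider spread of values on the Cre+ arrays would inflate such differences. After quantile normalization the mean was 2.87 (SE 0.37 over genes). The median difference was at most 0.41 in any of 10 classes of genes ordered by level, so this test could hardly have come out otherwise. The small size of these shifts itself argues against spread as the whole cause. Tim4-negative cells in the Cre- sorts would lower Timd4 with the other resident genes. Its difference was 0.12 (upper 95% limit 0.88, from limma over arrays), below the lower 95% limit of 2.30 for the mean of the 14 resident genes. The limit of 2.30 measures the spread between genes and not between arrays, so these limits are not of one kind. Another mix of macrophage kinds among the Tim4+ cells and an effect of targeting Abca1 and Abcg1 stay open, as untested.

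Cell cycle genes were higher in Cre+ by a mean of 1.18 over 30 genes. The mean was 0.97 (SE 0.11 over genes) after quantile normalization and 1.13 (SE 0.12) without Cre- replicate 1. Here too the shifts by level, at most 0.41, were too small for this normalization to remove the difference, which argues against array spread as the whole cause. On Cre- replicate 1 the list mean was 4.29, within the 4.26 to 4.71 of the other Cre- arrays. That array did not stand apart for these genes, so leaving it out could change little. More dividing cells among Cre+ macrophages may account for it, a hypothesis that was not tested.

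Markers of non-macrophage cells had a median difference of -0.25 over 69 genes, 1 of which rose and 6 of which fell. The central 95% of the medians of 10000 sets of genes matched on level ran from -0.23 to -0.13, with a middle value of -0.18. The markers lay just below that range, at percentile 0.34 of those sets. The sets were drawn gene by gene, so the range is too narrow if the markers vary together. A lower floor of values on the Cre+ arrays as the whole cause is therefore not excluded. Fewer such cells in the Cre+ sorts may account for part of the shift, but this stays open. Most of the markers (65.2%) lay below the median level of all genes, and their median was -0.12 after quantile normalization, so the size is uncertain; the sort removed cells bearing NK1.1, Ly6G, CD5 or CD19.

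In 20 of 320 groups of 4 arrays (6.25%; chance gives about 16), 1 array lay far from the other 3, with a gap of over 0.829 of the range. Cre+ replicate 2 was that array 7 times, Cre- replicate 1, Cre- replicate 3 and Cre+ replicate 1 3 times each, Cre+ replicate 4 2 times, and Cre- replicates 2 and 4 once each. On Cre+ replicate 2, Cd9 measured 9.66 (others 8.82 to 8.88), Ddit3 4.46 (5.64 to 5.86), Kdm5d 3.06 (2.40 to 2.51) and Ndufa4 11.59 (11.09 to 11.16). On the same array Retnla measured 8.60 (10.16 to 10.37), Uqcrc2 8.98 (8.41 to 8.49) and the mean of the mesothelial and fibroblast list 3.87 (3.62 to 3.65). On Cre- replicate 1, Col1a1 measured 4.67 (4.09 to 4.14), Lpcat3 6.47 (7.04 to 7.10) and Vwf 4.05 (3.56 to 3.60). On Cre- replicate 3, Alas2 measured 3.87 (3.58 to 3.62), Cd3e 4.01 (4.59 to 4.69) and Fosb 3.35 (3.91 to 4.01). On Cre+ replicate 1, Cldn5 measured 3.69 (3.21 to 3.24), Fabp5 8.96 (9.28 to 9.33) and Fcgr1 4.86 (5.96 to 6.01). On Cre+ replicate 4, the mean of the interferon gamma list was 6.36 (5.73 to 5.80) and that of the MHC class II list 6.75 (6.13 to 6.23). Cd93 measured 3.21 on Cre- replicate 2 (4.53 to 4.71), and Plac8 5.97 on Cre- replicate 4 (3.71 to 3.83).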

How the results depend on the processing

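The array spread as a covariate was chosen after seeing the data; it is higher on every Cre+ array, so it takes up part of any difference between them. Over 130 named genes and 18 alternative fits, 2068 results kept their side of the threshold, 195 fell below it, 39 rose past it and none reversed. A change of sign was counted as a reversal only where the main or the alternative fit passed. Where neither passed it was counted as kept, as for Abca1 (0.36, and -0.035 after quantile normalization). Over the 28 lists, with camera's estimated correlation and fry added, 486 kept their side, 45 fell below, 15 rose past and 1 reversed. Against 1526 genes (956 higher, 570 lower) and 13 lists, quantile normalization gave 996 genes, 550 higher, 6 lists, an Abcg1 difference of -1.11 and adjusted p = 5.0e-04 for the interferon gamma list. Median centring gave 224 lower genes and 0.0379 for that list, which had 0.0385 with genes from the 25th percentile of level. With genes from the median level up, 191 genes were lower and 4 lists passed, LXR targets not (0.0684), interferon gamma yes (0.00171). Trend and robust gave 1111 lower genes; array weights gave 948, and -0.81 for Abcg1. The array spread gave 143 genes (84 higher, 59 lower) and 5 lists, with 0.191 for LXR targets, 0.00352 for SREBP2 targets and type I interferon reversed to lower (0.722). With an estimated correlation 0 lists passed (LXR targets 0.185), and fry gave 0.0310 for interferon gamma. Leaving out 1 array gave 515 to 1352 genes, 414 to 920 higher and 93 to 432 lower. Lower genes were 354, 290 and 375 without Cre- replicates 1, 3 and 4, and 93, 332, 101 and 99 without Cre+ replicates 1 to 4. Higher genes were 490, 414 and 438 without Cre+ replicates 1, 3 and 4. Abcg1 then ran from -0.95 to -0.61, and the interferon gamma list from adjusted p = 0.00577 to 0.216. Fewer arrays or genes tested account for part of this; otherwise the cause was not tested.

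The replicate number as a block gave 666 genes, 581 higher and 85 lower, and ended the call of the fatty acid synthesis list (0.0512). No sign was seen that the numbers pair the samples: deviations of same-numbered arrays correlated at -0.179 to 0.064, 0 of 4 pairs over 0.1, and 2 of 8 arrays correlated best with their own number. With 4 pairs this cannot exclude a pairing, and the labels do not mention one. The table holds no signal over background, so how far dim genes can be trusted is not known.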

Other observations

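The gene families and single genes here were chosen only after their values were seen, while the tests of Lyz2 neighbours and X-linked genes were not. C-type lectin genes with Clec4 names moved apart in Cre+ macrophages. Of 11 measured, Clec4e, which encodes the receptor Mincle, rose from 5.53 ± 1.09 to 9.36 ± 0.45 (SD, n = 4 each; difference 3.82, SE 0.51, limma adjusted p = 0.00476), and Clec4d rose by 1.45 (SE 0.27). Clec4b1 fell by 3.24 (SE 0.48), Clec4a2 by 2.57 (SE 0.23), Clec4a1 by 2.29 (SE 0.20) and Clec4a3 by 0.89 (SE 0.20), and 5 did not pass. The call of Clec4d ended without Cre+ replicate 3 or 4 (adjusted p up to 0.0670) and after quantile normalization (0.0507). That of Clec4a3 ended without any one array other than Cre- replicate 1 (up to 0.0895), after median centring (0.0758) and with the array spread as a covariate (0.0719). No called member changed sign under quantile normalization or median centring. Of 27 integrin genes, 6 were higher, none was lower by limma and 21 did not pass. Beside Itga6, Itga9 rose by 2.35 (SE 0.26) and Itgb1, the beta 1 partner of both, from 8.23 ± 0.42 to 9.52 ± 0.12 (SD, n = 4 each), and these 3 calls held without any one array. With the array spread as a covariate Itga6 passed (adjusted p = 0.0326), while Itga9 (0.157), Itgb1 (0.0535) and Clec4e (difference 2.22, adjusted p = 0.303) did not. The calls of the other 3 integrin genes did not hold without single arrays. That of Itga4 (1.41, SE 0.30) ended without Cre- replicate 1 or 3 or Cre+ replicate 1, 3 or 4 (adjusted p up to 0.0973). That of Itgam (0.89) ended without Cre+ replicate 1 or 3 (up to 0.0585), and that of Itgb2 (0.62, SE 0.15) without any one array other than Cre- replicate 1 (up to 0.122) and after quantile normalization (0.15).

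A few single genes, picked because they rose and not tested as a group, encode proteins known as liver products. Hp, the haptoglobin gene, rose from 3.54 ± 0.76 to 7.14 ± 0.50 (SD, n = 4 each; difference 3.61, SE 0.39, limma adjusted p = 0.00211). F7, the factor VII gene, rose by 3.09 (SE 0.23), Orm1, an orosomucoid gene, by 2.93 (SE 0.28), Cp, the ceruloplasmin gene, by 2.57 (SE 0.22) and Cfb, the complement factor B gene, by 2.22 (SE 0.34). Mexis, an LXR-induced noncoding RNA gene next to Abca1, rose from 3.84 ± 0.37 to 5.91 ± 0.42 (SD, n = 4 each; difference 2.07, SE 0.25, limma adjusted p = 0.00328). These 6 calls held without any one array and after quantile normalization; with the array spread as a covariate only that of F7 did (adjusted p = 0.031).

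The Cre transgene lies in Lyz2, and a flanking region carried along with the LysM-Cre allele could change the expression of genes beside it. Of the 25 genes on each side of Lyz2, 0 of 50 passed limma's threshold, against 7.68% of other genes (one-sided Fisher's exact test for an excess, p = 1), and 16 of 50 (32.0%) had an unadjusted p under 0.05, against 33.4% of all genes. An excess of changed genes beside Lyz2 was therefore not found. Changes in only a few of these genes would not show as an excess, so a carried region is not excluded.

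Since Xist was higher in Cre+, a lower expression of X-linked genes was tested as a hypothesis. The median difference of 741 X-linked genes was -0.12, above the central 95% of sets matched on level, which ran from -0.157 to -0.128. The X-linked genes as a group were thus not lower than others.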
